A study of Mus musculus with 70 samples.

How the data were processed

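The authors deposited the RNA values as FPKM, made per the submitters' processing notes by aligning reads with TopHat and estimating expression with Cuffdiff. The p-value of each histone peak for daily rhythm and for amplitude was deposited by the authors, whose notes give alignment to mm10 with Bowtie2. Versions of these programs are not given in the sources used here. RNA came from epithelium taken by laser capture microdissection, chromatin from cells released with EDTA, and 16S libraries from faeces. Each RNA library pooled 3 mice, and no group had a replicate library at any time, so spread between replicate pools was not measured. The genotype p-values rest on how the difference between genotypes varied over the times. The rhythm p-values rest on how far the libraries departed from the fitted 24 h cosine. The SDs over the 4 times include differences by time of day.

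Samples were grouped by their labels, and the tests and gene lists were fixed before the data were examined. Genotype was tested with limma (version 3.58.1, R 4.3.3, moderated with a mean-variance trend) on log2(FPKM + 1) with Zeitgeber time as a block, on genes with a mean of at least 1 FPKM over the 8 fl/fl and ΔIEC libraries. Log2 changes are on that scale, which understates changes of low genes. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05, and all tests were two-sided. Rhythm was tested with limma F tests of a 24 h cosine and sine (2 degrees of freedom), with 2 residual degrees of freedom before moderation in fl/fl and ΔIEC, 1 in germ-free mice and 3 for the genotype test. The 21 gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation beside it, and with fry. Day-night ranges of lists were ranked among 10000 random lists matched on expression.

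Named genes were Hdac3, the 10 largest rises and 10 largest falls by genotype with a mean of at least 5 FPKM and the same direction at all times, 2 members of each list with the smallest p, all clock genes, and the 5 genes with the smallest rhythm p outside them. Other list members, other genes of the common cosine and the germ-free examples were chosen after their values were seen. Results of some genes under this rule are not reported here. Igha, Muc2, Sprr2a1 and Sh2d6 were not found in the tables, and Ciart, Slc51a, Slc51b, Mptx2 and Jchain were found under older symbols.

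The germ-free libraries are in a separately made table, so levels were compared without a test, by whether the 4 and 4 values overlapped, and after subtracting the median difference of all genes. The chromatin plan assumed values per library, whereas the peak tables hold p-values only, so the planned host, day-night and rhythm fits of H3K9ac and H3K27ac could not be run and the deposited p-values were counted and adjusted in their place. For the same reason no correlation of acetylation and RNA changes was made. Peaks were compared with bedtools 2.31.1 and assigned to a gene within 1 kb of either end, using gene positions on GRCm38, the build of mm10, and 99.3% of the tested RNA genes were matched. Of all peaks 73 (H3K9ac) and 65 (H3K27ac) lay on unplaced sequence. Other steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

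Faecal 16S libraries, 20 from a chow and high-fat diet series and 6 from a chow series, were not analysed here, because the 26 columns of values carry no label that ties them to a sample.

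The RNA tests were tested on simulated data with planted changes. The genotype test recovered 44% of genes at 1.5-fold, 92% at 2-fold, 98% at 4-fold and 100% at 8-fold, with 9 false calls among 10607 genes. Rhythm in fl/fl was recovered for 80% of genes at a log2 amplitude of 1 and 98% at 2, with 15 false calls and a median error of the peak time of 0.242 h. The rhythm difference was recovered for 21% and 97%, with 15 false calls among 133, of which 6 carried small RNA names that make up 0.952% of tested genes. The common cosine recovered 98% and 99% with 8 false calls. The list test called the 1 shifted list and 0 others. Simulated genes varied independently of each other, whereas the estimated correlation within real lists reached 0.938 (Paneth cell markers). The simulation therefore cannot judge false list calls in the real libraries. Simulated rhythms of the fl/fl and ΔIEC libraries were exact cosines, with noise of the size found in the genotype fit. In the real fl/fl libraries Nr1d1 (log2 amplitude 2.55, limma adjusted p = 0.365) and Tef (1.56, 0.234) did not pass, while Dbp (2.22, 0.0460) did. The recovered shares for rhythm may therefore be too high for the real libraries.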

Results

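Epithelial cells of the mouse ileum were profiled over the day to ask whether resident bacteria and the histone deacetylase HDAC3 shape daily rhythms of gene expression and histone acetylation in the intestine. The series holds 70 samples. RNA sequencing gave 12 libraries of laser-captured epithelium, 4 from germ-free wild-type mice, 4 from conventional Hdac3 fl/fl mice and 4 from conventional mice labelled HDAC3 ΔIEC, a label that denotes loss of Hdac3 from intestinal epithelial cells. Each of these groups was collected at Zeitgeber time (ZT, hours after lights on) 2, 8, 14 and 20, with 3 mice pooled into 1 library per group and time. Chromatin immunoprecipitation gave 18 libraries for acetylated lysine 9 of histone H3 (H3K9ac) and 14 for acetylated lysine 27 (H3K27ac), 2 marks of active promoters and enhancers. For H3K9ac, 6 libraries came from conventional mice, 4 from germ-free mice, and 2 each from fl/fl, ΔIEC, Myd88 mutant and Nr1d1 mutant mice. For H3K27ac, 6 came from conventional mice, 4 from germ-free mice, and 2 each from fl/fl and ΔIEC mice. The chromatin libraries of fl/fl, ΔIEC, Myd88 mutant and Nr1d1 mutant mice were taken at ZT8 and ZT20 only. Faecal 16S sequencing of 26 samples was not used in any comparison.

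The RNA tables listed 23288 genes each, of which 23263 were in both, as FPKM (fragments scaled to transcript length and library size). Summed FPKM ran from 664295 to 913353 in the 8 fl/fl and ΔIEC libraries and from 725738 to 773500 in the germ-free libraries. Read totals were not used here, and the depth of each library was judged against a ZT20 library of its table. It was taken from the commonest FPKM ratio of genes listed above 0 in both libraries and in few or no others. By that measure the germ-free ZT2 library was the shallowest of its table, at 0.240 of the depth of germ-free ZT20, and the others of that table lay between 0.889 and 1.15. The fl/fl and ΔIEC libraries lay between 0.725 and 1.11 of the depth of fl/fl ZT20. Markers of other cells varied between single libraries. Acta2, the smooth muscle actin, stood at 98.3 FPKM in fl/fl ZT2 and 81.8 FPKM in ΔIEC ZT14, against 5.27 to 24.6 FPKM in the other 6 libraries of that table. Myh11, smooth muscle myosin, stood at 29.6 and 29.4 FPKM in the same libraries and at most at 6.34 FPKM in the others. The Paneth cell lysozyme Lyz1 was at 1603 FPKM in fl/fl ZT2 and 401 FPKM in fl/fl ZT8, and between 42.3 and 238 FPKM in the other 6. Ptprc, which encodes the leukocyte antigen CD45, ranged from 4.25 to 6.52 FPKM in fl/fl and from 2.83 to 5.11 FPKM in ΔIEC.

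**Figure D1:**
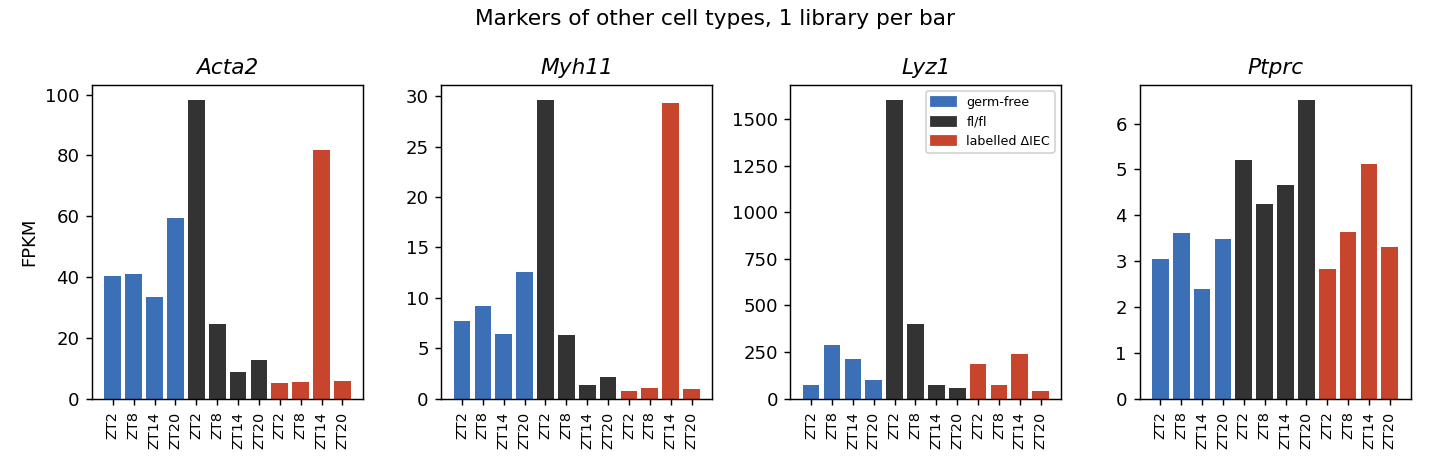
FPKM of the smooth muscle genes Acta2 and Myh11, the Paneth cell gene Lyz1 and the leukocyte gene Ptprc, with 1 bar for each of the 12 RNA libraries, coloured by group and ordered by Zeitgeber time. Acta2 reached 98.3 FPKM in fl/fl ZT2 and 81.8 FPKM in ΔIEC ZT14, and Lyz1 reached 1603 FPKM in fl/fl ZT2.

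The first comparison asked which transcripts differed between fl/fl mice and mice labelled ΔIEC. Hdac3 itself stood at 30.5 ± 5.15 FPKM in fl/fl and 33.9 ± 2.41 FPKM in the libraries labelled ΔIEC (mean ± SD, n = 4 times of day, log2 change 0.16, limma adjusted p = 0.490). An FPKM over the whole gene cannot check a deletion whose extent the labels do not give, so the direction of each difference below rests on the labels. Mt1, a metal-binding metallothionein, rose most in the libraries labelled ΔIEC, by 3.03 ± 0.31 on the log2 scale (± SE, adjusted p = 0.0153), from 567 ± 183 to 4589 ± 1390 FPKM. Areg, a ligand of the epidermal growth factor receptor, rose from 26.4 ± 12.2 to 195 ± 50.2 FPKM (log2 change 2.91, adjusted p = 0.0158). The calcium-binding protein gene S100g rose from 92.3 to 576 FPKM, the enolase gene Eno3 from 30.1 to 174 FPKM and the creatine kinase gene Ckb from 69.3 to 321 FPKM, with log2 changes of 2.79, 2.52 and 2.30 and adjusted p of 0.0266, 0.0282 and 0.0153.

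The largest falls were in genes of mixed function. Fut2, which adds fucose to epithelial glycans, fell from 37.99 ± 9.32 to 3.56 ± 1.84 FPKM (log2 change -3.17 ± 0.31, adjusted p = 0.0153). The acute-phase gene Saa1 fell from 1148 ± 551 to 129 ± 76.9 FPKM (log2 change -3.17, adjusted p = 0.0171), and Ang4, an antimicrobial ribonuclease, from 106 ± 108 to 12.03 ± 15.8 FPKM (log2 change -3.29, adjusted p = 0.0381). Ang4 was lower at all 4 times. It stood at 264 FPKM in fl/fl ZT2, the library highest in Lyz1, and at 16.5 to 80.1 FPKM in the other fl/fl libraries. Slc6a14, an amino acid transporter, had the smallest adjusted p of all genes (0.00299) and fell from 21.6 to 1.51 FPKM. The gasdermin genes Gsdmc2, Gsdmc4 and Gsdmc3 changed by -3.07, -3.07 and -2.26, and Pla2g4c and Maob by -2.55 and -2.16. Reads of the gasdermin, serum amyloid and defensin families can be shared between near-identical copies, so the split among their members is uncertain. The other genes chosen by the size of their change were 2210407C18Rik, 1700057G04Rik, 1600029D21Rik, Slc25a45 and Akr1b8, which rose by 1.94 to 2.45, and 1700011H14Rik, which changed by -3.07.

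In all, 198 genes rose and 165 fell among 10607 tested (limma, adjusted p under 0.05). All 363 had the same direction at the 4 times, which passing this test paired by time all but requires. The median absolute log2 change of these genes was 0.87, and that of all tested genes, with sign, was 0.01. Fl/fl and ΔIEC values did not overlap in 8.37% of genes, where chance gives 2.86%, and 2304 genes had an unadjusted p under 0.05, where 530 would by chance. The number past the adjusted threshold varied with the times included, being 1 without the ZT2 pair, 60 without ZT8, 74 without ZT14 and 83 without ZT20, while 1558 to 2326 genes had an unadjusted p under 0.05 in these fits. Without the ZT2 and ZT14 pairs, whose muscle markers stood apart, it was 153 (94 shared with the 363), and with every gene listed above 0 tested it was 0, with 2892 at an unadjusted p under 0.05.

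**Figure D2:**
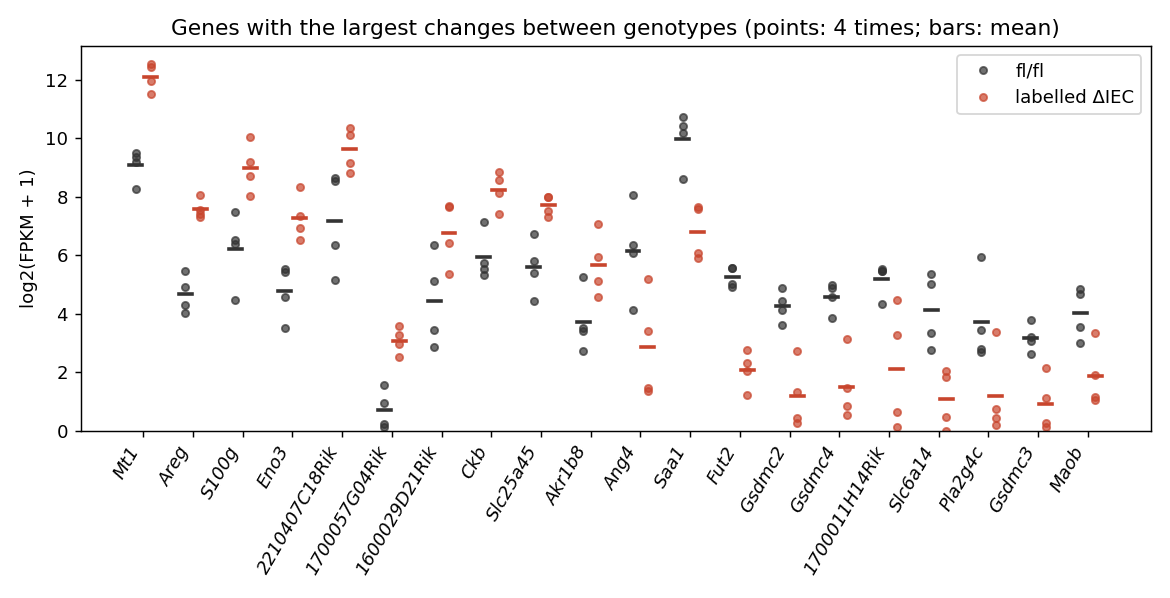
The 10 genes with the largest rise and the 10 with the largest fall in the libraries labelled ΔIEC, as log2(FPKM + 1), with 1 point per Zeitgeber time and a bar at the mean of the 4 times. Mt1 rose by 3.03 and Ang4 changed by -3.29 on this scale.

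Some genes for fat absorption were higher in the libraries labelled ΔIEC. Of 24 measured genes of lipid uptake and chylomicron assembly, 8 rose, 15 rose when adjusted over the list alone and none fell (median log2 change 0.60, camera adjusted p = 2.0e-08, adjusted p = 0.69 with an estimated correlation). Fabp1, the liver-type fatty acid-binding protein, rose from 1276 to 3199 FPKM (log2 change 1.60), Mttp, which loads lipid onto apolipoprotein B, from 337 to 748 FPKM (1.13), Apoc3, an apolipoprotein, from 1184 to 2467 FPKM (1.12), and Creb3l3, a transcription factor gene, from 183 to 426 FPKM (1.19). The sterol exporter genes Abcg5, Abcg8 and Abca1 rose by 0.94, 1.06 and 1.09, and Dgat2, which makes triglyceride, by 0.74. Of 19 genes of fatty acid oxidation and targets of PPAR, 6 rose, 12 when adjusted over the list alone and none fell (median 0.66, camera adjusted p = 2.5e-06, adjusted p = 0.69 with an estimated correlation). Angptl4, an inhibitor of lipoprotein lipase, rose by 1.50, the mitochondrial carnitine carrier Slc25a20 by 0.83, Acadl by 0.82, Hadhb by 0.67, Hadha by 0.66 and Cpt2 by 0.64. Among 15 genes of fatty acid synthesis 1 rose, Mlxipl (log2 change 0.69), and 1 did so when adjusted over the list alone, and Scd2 had a log2 change of 1.00 with an adjusted p of 0.113. In the cholesterol synthesis list Dhcr7 had a change of -0.49 (adjusted p = 0.0984). Without the ZT2, ZT8, ZT14 or ZT20 pair, 0, 1, 0 and 2 lipid uptake genes and 0, 0, 1 and 0 fatty acid oxidation genes rose over all genes. The median of the cholesterol synthesis list was 0.01, with camera pointing down and fry up, and it became 0.32 without the ZT14 pair (camera adjusted p = 0.0031).

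Some defence and antigen presentation genes were lower in these libraries. Of 18 measured genes of microbiota-responsive defence, 4 fell, 7 when adjusted over the list alone and none rose (median -0.36, camera adjusted p = 8.8e-04, adjusted p = 0.69 with an estimated correlation). The median of the defence list was -0.58 without the ZT2 pair and -0.18 without ZT8. Beside Saa1, Fut2 and Ang4, Saa2 fell from 4.10 to 0.385 FPKM (log2 change -1.79). The abundant lectins of this list had small changes, Reg3g from 28979 to 26540 FPKM (log2 change -0.08, adjusted p = 0.879) and Reg3b from 37705 to 30654 FPKM (-0.25, adjusted p = 0.560). Of 22 MHC class II and interferon genes, 5 fell over all genes, and 13 fell and 2 rose when adjusted over the list alone (median -0.58, camera adjusted p = 8.8e-04, adjusted p = 0.69 with an estimated correlation). H2-Aa fell from 1646 ± 278 to 599 ± 287 FPKM (log2 change -1.59, adjusted p = 0.0464), H2-DMb1 by 1.54, H2-DMa by 1.34, the guanylate-binding protein gene Gbp2 by 0.99 and Ciita, the master regulator of MHC class II transcription, by 0.91. Cd74, the invariant chain, went from 3488 to 1524 FPKM without passing (log2 change -1.25, adjusted p = 0.129), and the 2 members that rose when adjusted over the list alone were the interferon-induced Ifit2 and Isg15. Immune cell markers lay lower in the same libraries, with 0 of 14 past the threshold in limma, over all genes or over the list alone, 6 at an unadjusted p under 0.05 and a median of -0.49 (camera adjusted p = 8.8e-04, adjusted p = 0.69 with an estimated correlation). Paneth cell markers had 0 of 10 past the threshold in limma, over all genes or over the list alone, 6 at an unadjusted p under 0.05 and a median of -1.70 (camera adjusted p = 8.8e-04, adjusted p = 0.69 with an estimated correlation), with Defa17 at 195 FPKM in fl/fl and 44.8 FPKM in ΔIEC (adjusted p = 0.152) and Itln1 at 138 and 25.4 FPKM (adjusted p = 0.161). Over all genes 0, 2, 3 and 3 defence genes and 0, 5, 3 and 1 MHC class II and interferon genes fell without the ZT2, ZT8, ZT14 or ZT20 pair. Without ZT14, 3 Paneth cell markers fell, with 10 Paneth and 9 immune cell markers over the list alone, and without ZT2 the immune cell median was -0.31.

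Core clock genes were slightly higher on average in the libraries labelled ΔIEC. Of 11 measured, 2 rose, 3 when adjusted over the list alone (median 0.43, camera adjusted p = 0.0209, adjusted p = 0.69 with an estimated correlation). Without the ZT8 pair the median was 0.08 and the call was lost (camera adjusted p = 0.167), and without any 1 of the 4 times 0 core clock genes passed over all genes in limma. Nr1d1, which encodes the repressor REV-ERBα, rose from 30.4 to 55.7 FPKM (log2 change 0.76, adjusted p = 0.0480) and Npas2 from 9.74 to 14.9 FPKM (0.60, adjusted p = 0.0374). Among 8 clock output genes Usp2 rose (0.72, and 1 gene when adjusted over the list alone), and Dbp had a change of 0.59 (adjusted p = 0.168). All 7 of these list calls, for lipid uptake, fatty acid oxidation, the core clock, defence, MHC class II, Paneth cells and immune cells, were made with a preset correlation of 0.01, and fry, a rotation test of each list by itself, called 0 lists (lowest adjusted p = 0.104) with 5 lists at an unadjusted p under 0.05, while its test for change in either direction called 13. Without the ZT14 pair 14 lists were called. Of 8 splits that swap genotypes within times, the real one included, 5 gave as many called lists as the real split. The most in another split was 12, so the number of called lists did not set the real genotypes apart.

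**Figure D3:**
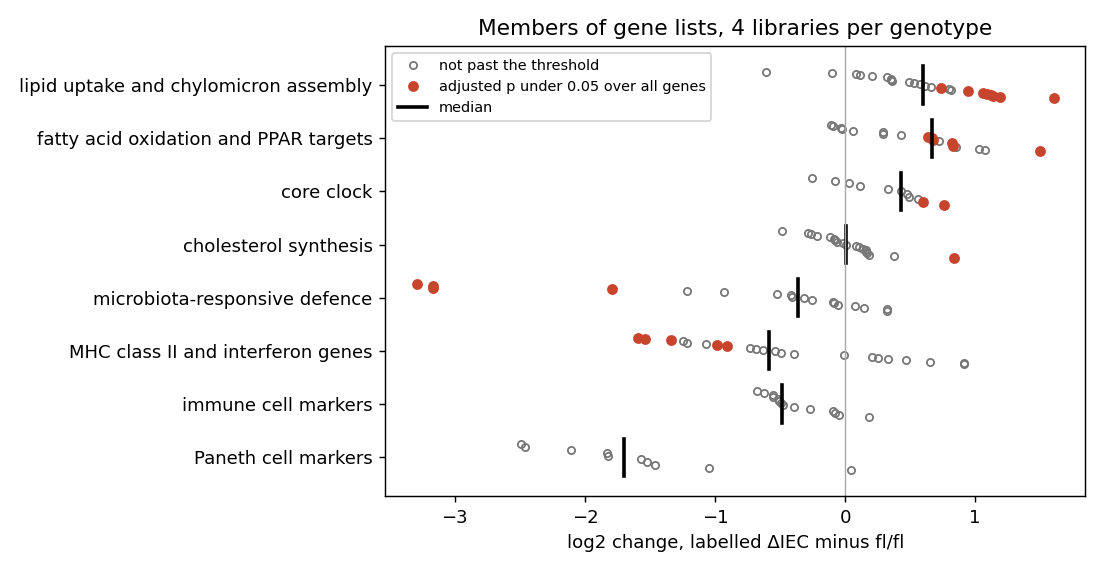
Log2 change (labelled ΔIEC minus fl/fl) of each measured member of 8 gene lists, with filled points for members past an adjusted p of 0.05 over all genes and a bar at the list median. The median was 0.60 for lipid uptake and chylomicron assembly and -1.70 for Paneth cell markers.

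The remaining lists were not called with all 4 times. Leaving out 1 pair called tuft cells without ZT2, oxidative phosphorylation (median 0.15, camera adjusted p = 0.0423) and goblet cells without ZT8, and immediate early and heat shock genes without ZT20. Without ZT14 it called fatty acid synthesis, cholesterol synthesis, transport, goblet cell, proliferation, stromal and immediate early genes. Alpi, the intestinal alkaline phosphatase, fell from 341 to 132 FPKM (log2 change -1.36) and the protease subunit gene Mep1a by 1.02, the only members of 15 brush border genes past the threshold over all genes, while over the list alone 4 rose and 3 fell. Slc1a1, a glutamate transporter, was the 1 of 18 nutrient and bile acid transport genes past the threshold (log2 change -0.98), and over the list alone 4 rose and 2 fell, with the glucose transporter Slc5a1 at 0.77 (adjusted p = 0.0861). Among 10 goblet cell genes Zg16 fell from 12392 to 4043 FPKM (log2 change -1.51), Spink4 rose by 0.75 and Spdef by 0.60 (over the list alone, 4 rose and 1 fell). The hormone genes Gip and Nts, with changes of -1.14 and -0.88, were the 2 of 9 enteroendocrine genes that fell (2 over the list alone), Rgs13 the 1 of 5 tuft cell genes (-0.86, with 2 over the list alone), Mcm6 the 1 of 13 proliferation genes (-0.64, with 1 over the list alone) and Egr1 the 1 of 15 immediate early and heat shock genes (-0.67, while over the list alone 8 rose and 2 fell). Tbl1xr1, a subunit of the corepressor complex that holds HDAC3, rose by 0.81 as the 1 of 10 genes of that list (1 over the list alone). In limma 0 of 24 oxidative phosphorylation genes (median 0.08), 0 of 5 stem and crypt progenitor genes (median -0.13, mean 0.05) and 0 of 15 stromal, endothelial and muscle genes (median -0.20) passed, over all genes or over the list alone, with 0, 0 and 1 at an unadjusted p under 0.05. Without the ZT2 pair these medians changed sign, to -0.01, 0.13 and 0.12, and without ZT14 the stromal list was called (median -0.28, camera adjusted p = 0.00194) with 5 members lower over the list alone.

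The next question was whether daily rhythms persisted in each group. Most core clock genes were rhythmic in fl/fl, ΔIEC and germ-free epithelium when adjusted over the list alone, and the germ-free rhythms were not tested against the others. Nr1d1 had a fitted log2 amplitude of 2.55 with a peak at ZT 8.27 in fl/fl, 2.79 at ZT 7.94 in ΔIEC and 2.47 at ZT 8.47 in germ-free mice. Dbp, a clock-driven transcription factor gene, had amplitudes of 2.22, 2.59 and 2.89 with peaks at ZT 11.6, 10.7 and 10.2, and passed over all genes in each group (limma adjusted p = 0.0460, 0.0158 and 0.0411). In fl/fl the Dbp call was lost without small RNA names (adjusted p = 0.0502) through the adjustment alone, with the same amplitude and a smaller unadjusted p, and over all alternatives its adjusted p ran from 0.0326 to 0.540 in fl/fl, 0.0186 to 0.268 in ΔIEC and 0.00669 to 0.101 in germ-free mice. Arntl, which encodes BMAL1, ran in the opposite phase, with amplitudes of 1.25, 1.16 and 1.52 and peaks at ZT 23.5, 22.3 and 23.3. Per2 peaked at ZT 16.7, 14.7 and 15.1 with amplitudes of 1.56, 1.51 and 0.82, and Tef at ZT 12.2, 11.4 and 11.2 with amplitudes of 1.56, 1.58 and 1.38. Of 11 measured core clock genes, 10 in fl/fl, 10 in ΔIEC and 9 in germ-free mice were rhythmic when adjusted over the list alone, and 7, 5 and 5 of 8 clock output genes were. Over all genes 0 core clock genes passed in limma in fl/fl or ΔIEC, with 10 and 10 at an unadjusted p under 0.05. Amplitudes were low for Clock in each group (0.40, 0.15 and 0.20) and for Cry2 in germ-free mice (0.81, 0.89 and 0.34). No core clock gene was shown to differ in rhythm between fl/fl and ΔIEC (limma, 0 over the list alone and 0 at an unadjusted p under 0.05). No clock output gene was when adjusted over the list alone (1 at an unadjusted p under 0.05). This test recovered only 21% of simulated differences with a log2 amplitude of 1. Fitted peaks lay earlier in ΔIEC for every tested core clock gene except Clock and Npas2, and for every tested clock output gene. That shared direction was not tested, and genes of the same libraries are not independent replicates. The median amplitude of the core clock list was 1.06 in fl/fl, 1.16 in ΔIEC and 0.90 in germ-free mice. Rora, Hlf and Bhlhe41 lay under the level needed for testing.

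**Figure D4:**
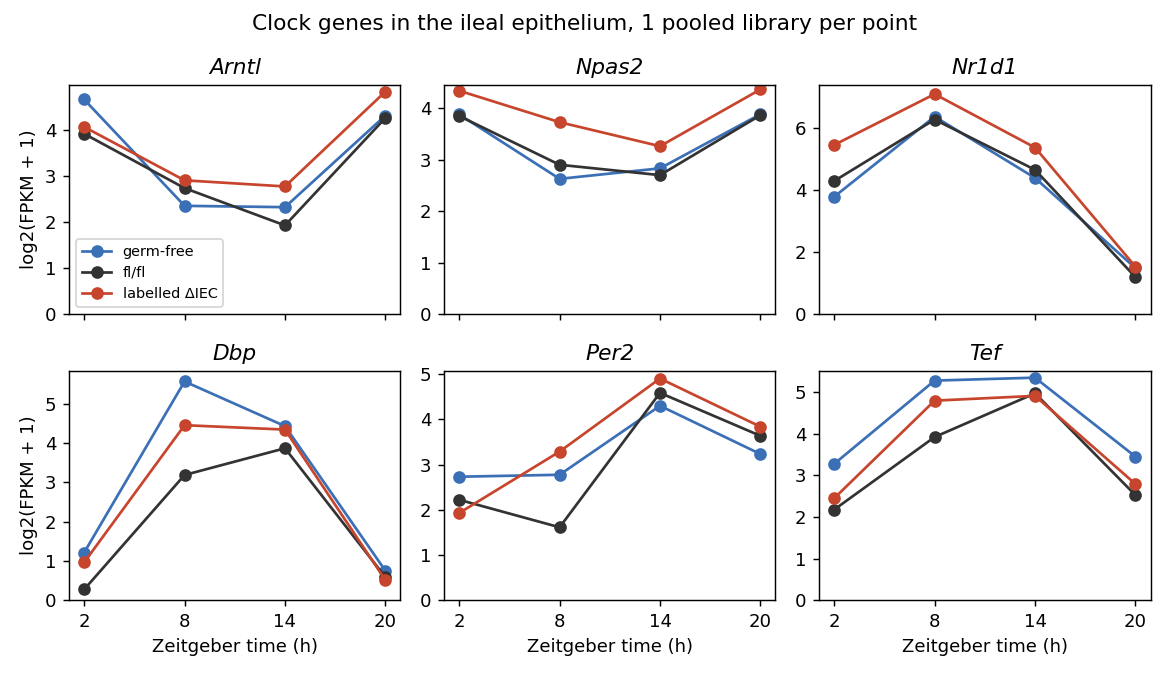
Log2(FPKM + 1) of Arntl, Npas2, Nr1d1, Dbp, Per2 and Tef by Zeitgeber time in hours, with 1 pooled library per point in germ-free, fl/fl and ΔIEC mice. Nr1d1 peaked near ZT8 and Arntl was lowest at ZT14 in each group.

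Across all genes, single groups of 4 libraries gave few rhythmic transcripts. In fl/fl 4 of 10607 genes passed, of which 3 were small RNA genes and the other was Dbp, and 1249 had an unadjusted p under 0.05 where 530 would by chance. In ΔIEC 5 passed, 4 small RNA genes and Dbp, with 711 at an unadjusted p under 0.05. In germ-free mice 22 of 10945 passed, 17 of them small RNA genes and the others Nr1d1, Nfil3, Nr1d2, Dbp and Gm129 (an older symbol of Ciart), with 914 at an unadjusted p under 0.05 where 547 would by chance. The germ-free fit has 1 residual degree of freedom and made 90 false calls among 290 on simulated values, 43 of them small RNA names. Its calls over all genes may therefore include false ones, and the germ-free counts over a list alone rest on the same p-values. How many of the 22 are false cannot be told, since the simulated false calls outnumbered all real calls. The difference in rhythm between fl/fl and ΔIEC passed for 7 genes, all small RNA genes, with 263 at an unadjusted p under 0.05 against 530 by chance. The smallest p outside the clock lists were those of Snord33, Snord16a, Snord22, Snora7a and Slc9a3 in fl/fl, and of Snord33, Mir25, Snord16a, Mir677 and Snora5c for the difference.

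A single cosine fitted to both genotypes, an alternative chosen after seeing the data, gave 81 rhythmic genes, none of them small RNA genes, with 2063 at an unadjusted p under 0.05. Dbp (amplitude 2.39, adjusted p = 0.00792), Tef (1.56, adjusted p = 0.00949), the sterol 27-hydroxylase gene Cyp27a1 (1.36, peak at ZT 13.2, adjusted p = 0.00792) and the nuclease gene Dnase1 (2.23, peak at ZT 5.36, adjusted p = 0.00792) were among them. It held 6 of 11 core clock genes, 10 when adjusted over the list alone, and 4 of 8 clock output genes, 7 when adjusted over the list alone. Core clock genes among them were Nr1d1 (adjusted p = 0.0261), Cry1 (0.0266), Per1 (0.0357), Npas2 (0.0380) and Cry2 (0.0480), and Arntl lay just outside (0.0537). Of 18 nutrient and bile acid transport genes 2 passed, 11 when adjusted over the list alone, with median amplitudes of 0.56 in fl/fl, 0.54 in ΔIEC and 0.43 in germ-free mice. Lipid uptake genes had 0 of 24 in limma over all genes and 7 over the list alone, with 6 in fl/fl and 4 in ΔIEC at an unadjusted p under 0.05. Cholesterol synthesis genes had median amplitudes of 0.62 in fl/fl, 0.18 in ΔIEC and 0.51 in germ-free mice, with 9, 0 and 10 of 19 at an unadjusted p under 0.05, but none passed in limma for the difference between fl/fl and ΔIEC (0 at an unadjusted p under 0.05), so the lower amplitude in ΔIEC was not shown to differ. When every gene above 0 was tested the common cosine gave 4 genes, and without small RNA names 169.

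Day-night changes were also set side by side without a test, since each group had 1 library per time. The log2 ratio of ZT8 to ZT20 correlated across 10242 genes with a Spearman coefficient of 0.40 between fl/fl and ΔIEC, 0.43 between fl/fl and germ-free and 0.31 between ΔIEC and germ-free. Over 19 clock genes it was 0.92, 0.88 and 0.98, with the same sign in 17, 18 and 18 of them. Genes are not independent replicates, so these coefficients describe the libraries. The median range over the 4 times was 0.51 on the log2 scale over all genes in fl/fl, 0.44 in ΔIEC and 0.38 in germ-free mice. For core clock genes it was 1.81, 2.06 and 1.75, above all 10000 random lists of matched expression in each group. This rank is not particular to the clock, since Paneth cell markers, which stood apart in single libraries, also reached percentile 100 in each group with ranges of 3.99, 2.77 and 1.88. In fl/fl, stromal and proliferation genes reached 99.95 and 99.97. Nutrient and bile acid transport genes ranged by 1.20, 1.34 and 0.79 (percentile 100 in each group) and cholesterol synthesis genes by 1.26, 0.65 and 0.96 (percentiles 100, 99.4 and 100). Brush border genes ranged by 0.92 in fl/fl and 0.83 in ΔIEC (percentiles 93.7 and 99.97) and by 0.36 in germ-free mice, at percentile 3.91.

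Germ-free and conventional fl/fl epithelium were compared to see which transcripts went with the presence of bacteria. Several genes of the defence and MHC class II lists, and Ubd, were far lower in germ-free mice. Saa1 stood at 4.84 ± 2.72 FPKM against 1148 ± 551 in fl/fl, the antibacterial lectin genes Reg3g at 1265 ± 268 against 28979 ± 9565 and Reg3b at 2578 ± 635 against 37705 ± 12105, the ubiquitin-like gene Ubd at 2.84 against 319 and Duoxa2, which matures the epithelial peroxide-forming oxidase, at 6.44 against 226 FPKM. Fut2 was at 2.60 against 37.99 FPKM, Nos2 at 18.1 against 131, H2-Aa at 287 against 1646 and Cd74 at 497 against 3488 FPKM. Other defence genes overlapped, among them Reg3a at 279 against 192 FPKM and Nlrp6 at 51.4 against 57.2 FPKM.

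By list, 14 of 19 defence genes and 15 of 22 MHC class II and interferon genes were lower in germ-free mice with no overlap between the 4 and 4 libraries, and none was higher. Their median log2 differences, relative to the median of all genes, were -2.75 and -1.24. Of 14 immune cell markers 10 were lower and 1 higher (median -2.03), of 10 Paneth cell markers 2 lower (median -1.49), of 13 proliferation genes 4 lower and 1 higher (median -0.81), and of 16 stromal, endothelial and muscle genes 6 were higher and none lower (median 0.46), and a different share of these cells was not separated from different expression per cell. Core clock genes overlapped in all but 1, which was higher, and no clock output gene was without overlap. Lipid uptake genes also overlapped (0 of 24 apart), with relative log2 differences of -2.75 for Fabp1, -1.77 for Apoa4 and -0.34 for Abcg5. Over 11311 genes, 2521 were higher and 721 lower without overlap, which makes 28.7% where chance gives 2.86%, and all genes together lay 0.18 higher on the log2 scale. With median-ratio scaling over both tables, an alternative chosen after seeing the data, 1158 were higher and 1375 lower, so the share of higher genes was 45.7% in place of 77.8%, while 15 defence and 16 MHC class II and interferon genes were lower. The tables had been made separately and were not tested against each other. Rps27 at 1054 FPKM in germ-free and 9.61 in fl/fl, Rpl34 at 19.5 and 841, and small RNA genes such as Mir3064 and Scarna2, listed at 0 in all fl/fl libraries, differ between the tables by amounts whose cause was not tested.

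For histone acetylation the files hold the authors' p-values for each peak and no values per library, so neither levels nor directions are reported. The authors' deposited table for H3K9ac lists 17814 peaks on mm10, with a median width of 2735 bp, and that for H3K27ac lists 18628 peaks with a median of 2472 bp. In the authors' deposited tables every listed peak has a circadian p in conventional mice of at most 0.0329 (H3K9ac) or 0.0186 (H3K27ac), so the lists hold peaks rhythmic in conventional mice. Of the H3K9ac peaks in the authors' deposited table, 3266 (18.3%) had a circadian p under 0.05 in germ-free mice where 891 would by chance, and 0 passed after Benjamini-Hochberg adjustment. Of the H3K27ac peaks in the authors' deposited table, 678 (3.64%) had such a p where 931 would by chance, and 7 passed after adjustment. With the H3K27ac peaks of the authors' deposited table in 4 equal groups by width, 13.1% of the narrowest had such a p, against 0.923%, 0.344% and 0.193% of the wider ones. Conventional mice were sampled at 6 times and germ-free mice at 4, so the p-values of these groups rest on different numbers of libraries, and their difference was not tested. Since every listed peak has a small conventional p, the lists hold no peaks rhythmic in germ-free mice alone. The germ-free shares therefore do not measure a loss of rhythm. The H3K9ac amplitude p of the authors' deposited table was past the same adjustment at 12509 peaks (70.2%) for wild type and hdac3, 10346 (58.1%) for nr1d1 and 14852 (83.4%) for myd88, and that of H3K27ac at 7666 peaks (41.2%) for hdac3. The labels give 1 library per host and time for these mutants, so no spread between replicates was measured, and such p-values in the authors' deposited tables do not show that the hosts differ. These mutants were sampled at ZT8 and ZT20 only, so a changed amplitude cannot be told from a changed peak time. In the authors' deposited table, hdac3 and nr1d1 were both past adjustment at 7547 H3K9ac peaks where 7265 would be if independent, and nr1d1 and myd88 at 9856 where 8626 would. Whether the same wild-type libraries entered each p is not given in the sources used here.

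**Figure D5:**
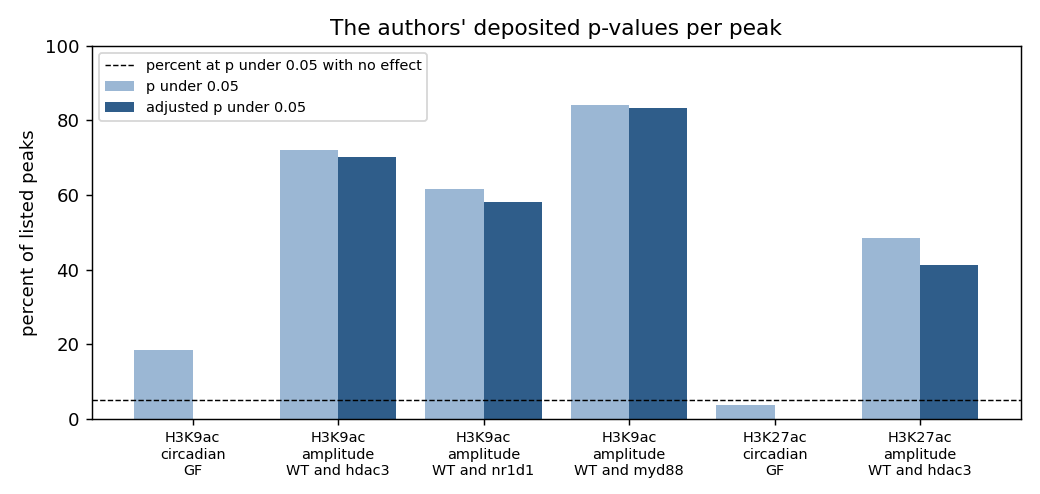
Percent of listed peaks with a p under 0.05 (light) and an adjusted p under 0.05 (dark) for each of the authors' deposited p-values outside the conventional circadian one, with a dashed line at the 5 percent that chance gives. Germ-free circadian p-values were under 0.05 at 18.3% of H3K9ac and 3.64% of H3K27ac peaks, and amplitude p-values for wild type and hdac3 passed adjustment at 70.2% and 41.2%.

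Listed peaks at the ends of core clock and lipid uptake genes were looked up, and their shares past adjustment were not tested against those of all peaks. In the authors' deposited table the H3K9ac peak at the end of Hdac3 (chromosome 18, 37952339 to 37956303) has a circadian p of 2.3e-04 in conventional and 0.224 in germ-free mice and an amplitude p of 2.6e-04 for hdac3. Of 12 core clock genes, 11 had H3K9ac peaks within 1 kb of a gene end in the authors' deposited table, 12 peaks in all, of which 7 passed for hdac3, 7 for nr1d1, 10 for myd88 and 2 had a germ-free circadian p under 0.05. Those 2 were at Npas2 (chromosome 1, 39192079 to 39198350) and Arntl (chromosome 7, 113177051 to 113180941), with germ-free p of 0.00915 and 0.0392 and hdac3 amplitude p of 4.0e-21 and 1.4e-20 in the authors' deposited table. For nr1d1 the same Arntl peak has an amplitude p of 0.503 in the authors' deposited table. The Cry1 peak (chromosome 10, 85182506 to 85186523) has an hdac3 amplitude p of 8.7e-17 and the Nr1d1 peak (chromosome 11, 98771619 to 98777906) one of 0.383 in the authors' deposited table. Lipid uptake and chylomicron genes had 23 such H3K9ac peaks at 20 of 24 genes, of which 12 passed for hdac3, 12 for nr1d1 and 18 for myd88, and 1 had a germ-free circadian p under 0.05 in the authors' deposited table. Apob (chromosome 12, 7976964 to 7984671), the structural protein of chylomicrons, has an hdac3 amplitude p of 6.6e-27, Fabp1 (chromosome 6, 71199478 to 71202703) one of 6.2e-08 and Mttp (chromosome 3, 138141972 to 138145882) one of 1.4e-04, with 3.2e-30 at Mttp for nr1d1, in the authors' deposited table. For Apoa4 (chromosome 9, 46239077 to 46244674) and Plin2 (chromosome 4, 86668408 to 86671332) it is 0.599 and 0.741, and for the 2 Abcg5 peaks 0.00613 and 0.899, in the authors' deposited table. Among fatty acid synthesis genes Me1 (chromosome 9, 86694928 to 86696627), which makes NADPH, has an hdac3 amplitude p of 8.85e-43 in the authors' deposited table. Cholesterol synthesis genes had 19 H3K9ac peaks at 17 of 19 genes, 6 with a germ-free circadian p under 0.05 and 13 past adjustment for hdac3 in the authors' deposited table. Stromal, endothelial and muscle genes had none at 16 genes in either authors' deposited table, and immune cell markers 2 H3K9ac peaks at 15 genes. H3K27ac peaks lay at 11 of 12 core clock genes in the authors' deposited table, 12 peaks of which 6 passed for hdac3 and 0 had a germ-free circadian p under 0.05.

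The peaks with the smallest p outside these lists were varied. For the conventional rhythm of H3K9ac it was a peak at Cutal (chromosome 2, 34873823 to 34875619, p = 1.2e-08) and for the germ-free rhythm one at Srsf1 (chromosome 11, 88046304 to 88051105, p = 1.5e-05), a splicing factor gene, in the authors' deposited table. Peaks at Gkap1 and Trappc8 followed for the germ-free rhythm, and peaks within Shroom3 and Slc41a2 for the conventional one, in the authors' deposited table. For H3K27ac in germ-free mice it was a peak at the transfer RNA gene n-TEctc7 (chromosome 1, 171078081 to 171078623, p = 6.4e-09), followed by 1 within Tusc3 and 1 at Gm46069, in the authors' deposited table. The conventional rhythm of H3K27ac had its smallest p, 2.0e-06, at tied peaks of the authors' deposited table that include those at Arsk and Ttc37 and at Glipr2. For hdac3 the amplitude p of H3K9ac is listed as 0 at 4 peaks of the authors' deposited table, 3 of which lie outside annotated genes, for example chromosome 12, 3109457 to 3110534.

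Of the H3K9ac peaks 82.5% overlapped an H3K27ac peak by at least 1 bp, and of the H3K27ac peaks 80.6% overlapped an H3K9ac peak. With a reciprocal overlap of 50 percent these shares were 72.6% and 69.4%. Among the 50% of peaks of each list with the smallest conventional circadian p in the authors' deposited tables they were 44.2% and 42.9%. Within 1 kb of a gene end lay 64.3% of H3K9ac and 56.0% of H3K27ac peaks. Genes whose RNA rose or fell in the libraries labelled ΔIEC were not shown to differ from other genes in how often an H3K9ac end peak had an amplitude p past adjustment, 75.5% of 278 against 76.8% of the others with a listed end peak (Fisher's exact test, two-sided, odds ratio 0.93, adjusted p = 0.615). For H3K27ac they did so less often, 45.4% of 249 against 53.8% (Fisher's exact test, odds ratio 0.71, p = 0.00979, adjusted p = 0.0196), and with all peaks at a gene counted the odds ratio was 0.76 and the adjusted p 0.0558. Both shares rest on the amplitude p of the authors' deposited table, which has no direction and no replicate libraries behind it, and genes are not independent replicates. Genes with RNA rhythm in the common cosine, such as Dbp and Tef, had a listed H3K9ac end peak in 61 of 80 cases, fewer than matched sets of genes (mean 89.2%, range of the central 95% from 82.5% to 95%). For H3K27ac it was 72.5% against 85.4%, and for genes that rose or fell by genotype 77.4% against 88.7% (H3K9ac) and 69.4% against 84.5% (H3K27ac).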

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

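The test of short genes with few reads and that of rhythm outside the small RNAs were chosen after the result was seen. The 24 h rhythm differed between fl/fl and ΔIEC for 7 genes by a limma test of the difference itself, all with small RNA names. The adjusted p was 0.00147 for Snord33 and for Mir25, 0.00261 for Snord16a, and 0.00286 for Mir677 and for Snora5c.

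Few reads in very short genes could produce these differences: the 7 genes were listed at 0 in a median of 6 of the 8 libraries, against 0 for 667 genes of the same mean FPKM, 97.3% of which had no library at 0. These zeros are also what gave the calls, and reads and gene lengths were not measured, so the explanation stays open. The 8 splits that swap genotypes within times, a restriction also chosen after the result was seen, are too few for a share under 0.05 (7 calls in the real split, up to 22 in another, 4 of 8 with as many). A change of rhythm outside the small RNAs could not be told from none. Without small RNA names 0 genes passed and 296 had an unadjusted p under 0.05, fewer than the 525 that chance gives and within the 75 to 1369 of the other 7 splits made within times. A real difference of daily rhythm between genotypes may exist and would need replicate libraries at each time, since only 21% of simulated differences with a log2 amplitude of 1 were recovered.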

How the results depend on the processing

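Settings without the ZT2 and ZT14 pairs or without small RNA names, the common cosine and all germ-free level settings were chosen after the results were seen. Genotype calls (363) became 0 with no filter on low values, 22 with no block for time, 1 (without ZT2) to 83 (without ZT20) when a time was left out, 153 without the ZT2 and ZT14 pairs and 574 without small RNA names. Called lists (7) became 0 with an estimated correlation, 0 with fry, 8 (without ZT2) to 14 (without ZT14) when a time was left out and 14 without the ZT2 and ZT14 pairs. Olfm4 ranged from -0.13 (without ZT14, reversed) to 1.82 (without ZT2). The cholesterol synthesis list ranged from -0.11 (without ZT8) to 0.32 (without ZT14), with 0.30 without the ZT2 and ZT14 pairs, the last 2 reversed against the direction camera gave. The common cosine over the 8 fl/fl and ΔIEC libraries, a fit of both genotypes and not a count for fl/fl, gave 81 genes. Rhythm calls in fl/fl (4) became 2 with no filter and 0 without small RNA names. In ΔIEC (5) they became 9 with a pseudocount of 0.1 FPKM, 3 with no filter, 3 with a mean of at least 5 FPKM and 1 without small RNA names. The rhythm difference (7) became 4 with no filter and 0 without small RNA names, germ-free rhythm (22) became 5 and 5, and the common cosine (81) became 4 and 169. Day-night correlations became 0.46 (fl/fl and germ-free) and 0.35 (ΔIEC and germ-free) at a mean of at least 5 FPKM. With median-ratio scaling 1158 genes were higher and 1375 lower in germ-free mice. Shared peaks became 72.6% (H3K9ac) and 69.4% (H3K27ac) with a reciprocal overlap and 44.2% and 42.9% for the 50% of peaks with the smallest conventional circadian p, and the H3K27ac odds ratio became 0.76 with all peaks of a gene. The cause was not tested. Alternatives planned for the H3K9ac and H3K27ac host, day-night and rhythm fits and for all 16S tests were not run. The RNA genotype test is paired by time. For 16S: No paired analysis was possible because the columns carry no sample label.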

Other observations

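The tests of peak width and of repeated sequence, and the restriction of the splits to swaps within times, were chosen after the result was seen. The genotype test pairs the libraries by time, and the 8 splits that swap genotypes within times are too few for a share under 0.05. The real split gave 363 genotype calls and at most 1 came from another (1 of 8 with as many), and it gave 7 called lists where another gave 12 (5 of 8 with as many). The number of called lists therefore did not set the real genotypes apart from swapped labels. The common cosine gave 81 genes in the real order of the times and at most 7 in another, 1 of 3 orders having as many, which is too few orders to judge.

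The lower defence and MHC class II genes of the libraries labelled ΔIEC could come from fewer immune cells, fewer Paneth cells, scaling of the libraries or a change within epithelial cells. The mean of 40 members differed by -0.61 (95% interval -1.17 to -0.06). With immune cell markers as a covariate it was -0.46 (-1.71 to 0.79) and with Paneth cell markers -0.49 (-1.62 to 0.65), so neither can be told apart from a change within the epithelium. Scaling of the libraries is unlikely, because the median change stayed at -0.45 or lower under 2 other scalings.

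The smallest H3K9ac amplitude p-values of the authors' deposited table might mark reads piled up at repeated sequence. Of the 20 peaks with the smallest hdac3 p, 7 lay at no gene against 12.2% of all peaks, and 11 were among the 1 percent smallest for nr1d1 and myd88. The first share falls short of the level set and cannot tell. A germ-free circadian p between 0.35 and 0.37 was listed for 5 of these 20 peaks, against 1.68% of all peaks. Those 5, on chromosomes 12, 14, 2 and 9, were also the peaks with the smallest hdac3 p. Their conventional circadian p ran from 0.00139 to 0.00174 in the authors' deposited table, so they shared nearly the same values. A conventional circadian p between 0.001 and 0.002 was listed for 7 of the 20 peaks, against 20.2% of all peaks. These shares were not tested, and repeated sequence stays open. For hdac3, peak width by itself is an unlikely source, with a Spearman correlation of width and p of -0.0551 across peaks. Peaks are not independent replicates. The median width was 2661.5 bp in the 20 peaks against 2735 bp in all. Reads per peak were not available, so whether more reads gave the small p was not examined. For nr1d1 and myd88 the correlations were -0.163 and -0.225, and wider peaks stay open there. Values per library would settle it.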
